A study of Arabidopsis thaliana with 9 samples.

How the data were processed

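RNA was extracted from inflorescences with an RNeasy Plant Mini Kit, labelled with biotin and hybridised to Affymetrix arrays, per the labels. GCOS is named in the submitters' processing notes, without a version or a scaling target. The deposited values are linear ratios, for most rows to the probe set's own median over the 9 arrays, as read from the values. The row median is exactly 1 in 15112 of 22810 rows (66.3%), under 1 in 7698 and over 1 in 0. What the 7698 rows were divided by is not stated. How dim probe sets were handled and how the arrays were scaled is not stated. The smallest deposited ratio is 0.01, held by 123 values, and the largest is 38.8. The design had allowed for signal intensities, so 3 of its choices mean less on a ratio: the filter on low values, the trend of the prior variance, which follows the mean log ratio here, and the rule that takes the probe set with the highest mean for a gene.

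The log2 of the deposited ratio was used with no offset. The medians of the arrays' log2 values spanned 0.218, within the 0.3 allowed beforehand, so the arrays were used as deposited. The 64 control probe sets were left out of the tests and examined apart. A probe set was kept when its value was above its array's 40th percentile on at least 3 of 9 arrays, which kept 17273 of 22746. Of those kept, 15062 have a median of 1 and 2211 a median under 1. A probe table names 1 gene for 13513 probe sets, several for 503 and none for 8730. Of the probe sets kept, 9628 have 1 gene, 355 several and 7290 no name, with 9491 distinct genes. Of the 13513, 13436 matched the gene table of the assembly TAIR10.1, which was used for names only. RGA, RGL2 and GA1 were to be read first as a check of the labels and are not analysed here, since the probe table pairs no probe set with their names.

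Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend, two-sided, Benjamini-Hochberg over the probe sets kept, threshold 0.05) in a single fit over 3 groups of 3 arrays with 6 residual degrees of freedom. An exact permutation test of 3 arrays against 3 cannot go below p = 0.1, so none was used for single genes. The fit was tested on simulated data, 20 sets of 17273 probe sets with 200 changed. It recovered 9.3% of 2-fold and 35.1% of 4-fold changes for RGA-GR Dex against RGA-GR mock, with a mean of 1.65 false calls, and 10.2% and 36.1% for RGA-GR Dex against nontransgenic Dex, with 2.35. Chance values for comparisons that share arrays came from simulated unchanged groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

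Before the data were examined, 23 gene lists were fixed, with 302 loci. The probe table names 43 of these loci, and 38 genes were measured. The lists of GA biosynthesis, GA inactivation, floral organ identity, shoot meristem, jasmonate response and brassinosteroid have 0 measured members and give no value. Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01 and with an estimated correlation, with Benjamini-Hochberg over 4 sets. Only the GA perception and signalling list reached that size among the fixed lists, and the other 3 sets (wider pollen and tapetum lists and plastid-encoded genes) were made afterwards, as were 36 gene families. Named genes were chosen by a rule fixed beforehand: among probe sets with 1 gene, past 0.05 in both Dex comparisons the same way and with the RGA-GR Dex arrays all above or all below the others, the 12 largest rises and 12 largest falls. It also took up to 4 members of each list with the lowest adjusted p for Dex against mock, and the 5 largest rises and 5 largest falls in each of the other comparisons. The first part of the rule named 0 genes. The genes described as picked after their values were seen, the genes named from the sets made afterwards, and GH3.9 and GH3.17, fall outside it.

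The labels number the arrays 1 to 3 in each group, and the design text speaks of independent sets. Deviations from the group means correlated across probe sets between the mock and Dex arrays of the same number (r = 0.332, 0.118 and 0.325), while the highest correlation with another number was -0.041. Deviations within a group cancel out, which makes correlations with other numbers negative on average, so only the same-number values speak for pairs. On those values, mock and Dex arrays of the same number were taken as pairs, from the data and not from the labels. Numbers of nontransgenic arrays did not pair with those of the transgenic line (r from -0.039 to 0.036). The fit has no block, as fixed beforehand.

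The alternatives planned were quantile normalization, array medians subtracted, an offset of 0.0894 (0.1 of the table median) before log2, no filter, a filter at the 60th percentile, eBayes without trend, eBayes with trend and robust, only the 6 arrays compared, a replicate block over all 9 arrays, a 2-fold minimum, and each array left out in turn. Added after seeing the data were a replicate block within the transgenic line (for the lists also with an estimated correlation), the same in its 6 arrays, presence of poly-A spike-in signal as a block, fits to the 4 arrays without and the 5 arrays with that signal, and a fit without both arrays of pair 2 of the transgenic line. The spike-in batch was read from 24 control probe sets, whose mean ratio was 0.0748 to 0.128 on transgenic replicates 1 and 2 and 0.806 to 2.30 on the other 5 arrays. No mock-treated nontransgenic group is among the samples, so no interaction of transgene and Dex was fitted.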

Results

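Transcript levels were measured on 9 Affymetrix arrays hybridised with RNA from Arabidopsis thaliana inflorescences, from which flowers past stage 12 had been left out. All plants carried the ga1-3 rga rgl2 background, in which gibberellin (GA) synthesis is blocked and the DELLA repressors RGA and RGL2 are lost. The transgenic line also carried RGA fused to the glucocorticoid receptor (RGA-GR), so that dexamethasone (Dex) brings RGA activity back. There were 3 groups of 3 arrays, each sampled at 4 h: the transgenic line under mock treatment (RGA-GR mock), the transgenic line under Dex (RGA-GR Dex), and nontransgenic plants under Dex (nontransgenic Dex). Of 22746 probe sets, 17273 passed the filter on low values, and 9628 of these carry the name of 1 gene. Deposited values are ratios, for most probe sets to the probe set's own median over the arrays, so values compare arrays and not genes. Of the probe sets kept, 2211 have a median ratio under 1, those of DFR and UF3GT among them, and their divisor is not known. The number of arrays limits the precision, and the median standard error of a difference was 0.26 on the log2 scale. Differences below are log2 differences between group means (n = 3 arrays per group). Their SE is the moderated SE from limma, pooled over the 9 arrays. For control probe sets the SE comes from the SDs of the groups compared. Adjusted p values come from limma with Benjamini-Hochberg over all probe sets kept unless another family is named.

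The first comparison, RGA-GR Dex against RGA-GR mock, asks which transcripts respond to RGA activity. Its groups also differ in Dex itself, and this comparison alone cannot set a response to Dex apart from one to RGA. The GA receptor gene GID1B was 2.04-fold higher after Dex (1.03 ± 0.20) and higher in all 3 pairs of arrays, by 0.57, 1.39 and 1.12. DFR, which encodes an enzyme of anthocyanin synthesis, was 6.38-fold lower (-2.67 ± 0.52), and JMT, which encodes the methyltransferase that makes methyl jasmonate, was 2.17-fold lower (-1.12 ± 0.36). Across the genes of GA perception and signalling, 8 of 8 measured members had higher means after Dex, with a median of 0.31. Over all probe sets, none of these genes passed the test, the adjusted p being 0.453 for GID1B and DFR and 0.533 for JMT. Adjusted over the list alone, GID1B, DFR, JMT and the calmodulin-like gene CML38 (1.14 ± 0.42) passed in limma with Benjamini-Hochberg. The list of GID1B has 8 measured genes and those of DFR, JMT and CML38 have 2 each. An adjustment over 2 genes is slight, and none was made across the lists, so these passes are weak evidence.

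No probe set passed an adjusted p of 0.05 with limma in this comparison, where the smallest adjusted p was 0.143. At an unadjusted p under 0.05 there were 1525 probe sets, 881 higher and 644 lower after Dex, where 5% of those tested is 864. In 1258 probe sets all RGA-GR Dex arrays lay above all RGA-GR mock arrays and in 730 all lay below, together 1988 or 11.5%, where exchangeable arrays give 10%. Mock and Dex arrays of the same number are alike, so 864 and 10% are not the values without a change: the other 3 splits of these 6 arrays that part all 3 pairs gave 425 to 766 probe sets at an unadjusted p under 0.05 and 727 to 1188 fully separated. Such splits are too few for a test. The 25S rRNA control signal was also higher after Dex, by 2.60 ± 1.67 and in all 3 pairs. The preset camera test placed the GA perception and signalling list above other genes (adjusted p = 0.00076), while the adjusted p was 0.227 with an estimated correlation. On simulated data for this comparison, with 200 of 17273 probe sets changed, the limma test recovered 9.3% of 2-fold and 35.1% of 4-fold changes. The count rose to 15 without RGA-GR Dex replicate 1 and to 1 with eBayes without trend. A batch that the labels do not name, read from the poly-A spike-in signals, put transgenic replicates 1 and 2 apart from the other arrays: the count was 0 with the batch as a block, 0 in the 4 arrays without that signal and 50 in the 5 arrays with it, which hold 1 array of each transgenic group and take their spread from the nontransgenic arrays.

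Among the other lists, means after Dex were higher for the auxin conjugating enzyme gene GH3.3 (0.54 ± 0.23) and lower for the expansin gene EXPA8 (-2.47 ± 0.92) and for EXL5 (-1.48 ± 0.66), a gene of the pollen coat, and none of these passed. Pair 1 showed little of the falls, with -0.22, -3.05 and -4.15 in the 3 pairs for EXPA8 and -0.21, -2.09 and -2.15 for EXL5. The medians were 0.18 over 4 measured DELLA targets known from seedlings, -0.09 over 3 stamen regulators, -0.64 over 2 genes of tapetum and pollen wall, -0.10 over 2 of photosynthetic tissue, -0.41 over 2 of jasmonate biosynthesis, 0.54 over 3 of auxin response and -0.33 over 4 of cell wall loosening. They were 0.00 over 2 of abscisic acid and cold response, -0.23 over 2 of the cell cycle, -1.34 over 2 of flavonoid synthesis and 0.72 over 2 of touch and wounding. With 1 measured gene each, the values were -0.07 for pollen (MGH3), -0.21 for trichomes (TRY), 1.75 for defence (PDF1.2, from 0.22 to 3.93 in the pairs), 0.42 for heat shock (HSP22) and 0.37 for the circadian clock (GI). In these lists no member passed over all probe sets, and adjusted over the list alone GID1B also passed among the DELLA targets. Few genes of pollen and tapetum in the lists fixed beforehand carried a name, so wider lists were written after the data were seen. In these, 14 of 18 pollen genes had lower means after Dex (median -1.15) and 16 of 22 tapetum genes did (median -0.37), and none passed singly. The preset camera adjusted p was 0.00038 for pollen and 0.0007 for tapetum, against an adjusted p of 0.227 for both with an estimated correlation, and in the 4 arrays without spike-in signal the preset value for tapetum was 0.133.

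Single genes were also picked after their values were seen: those at an unadjusted p under 0.01 after Dex, past the adjusted threshold in RGA-GR Dex against nontransgenic Dex, and with the RGA-GR Dex arrays all above or all below the other 6. There were 52 such rises and 38 such falls. The largest fall was in AT5G28090, 33.1-fold lower (-5.05 ± 0.95), the 1 gene called with eBayes without trend. Its log2 ratios on the RGA-GR Dex arrays, -5.14, -4.95 and -4.84, lie at the low end of the deposited values, so its fold and rank are uncertain. Against nontransgenic Dex its difference ran from -4.44 to -2.52 over the alternatives. AT2G18720 (-3.34), AT3G18260 (-3.20), AT1G30795 (-3.02), AT3G48490 (-2.48) and AT3G28610 (-2.25) came with it. All of these falls but AT3G48490 come from probe sets with a median ratio under 1, whose divisor is not known. Means were higher for AT1G25400 (1.85), the peroxidase gene AT5G39580 (1.52), AT1G15330 (1.52), the beta-glucosidase gene BGLU46 (1.45), AT2G28570 (1.35) and PPDK (1.21), which encodes pyruvate orthophosphate dikinase. None of them passed the adjusted threshold for Dex against mock.

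**Figure D1:**
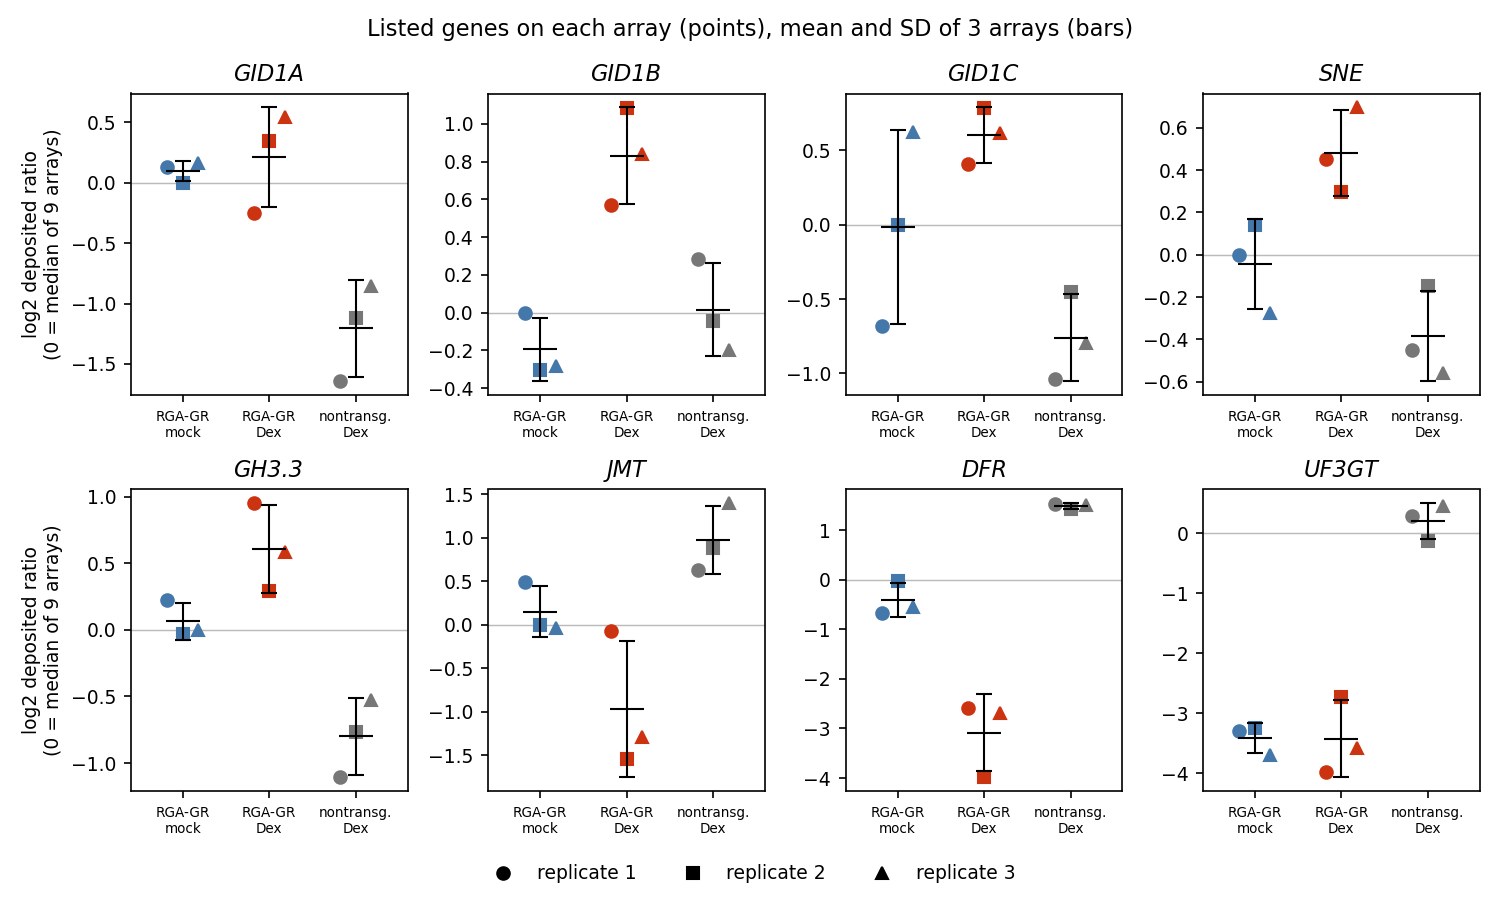
Log2 of the deposited ratio (vertical axis) for 8 listed genes on each array, by group (horizontal axis). The axis label, 0 as the median of the 9 arrays, does not hold for DFR (median -0.55) and UF3GT (median -3.25). Points are arrays, shaped by replicate number, and bars give the mean and SD of 3 arrays. GID1B is 2.04-fold higher and DFR 6.38-fold lower in RGA-GR Dex than in RGA-GR mock, and neither difference passes over all probe sets.

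The second comparison, RGA-GR Dex against nontransgenic Dex, holds Dex constant and asks what the transgene with its activated product changes. The 3 GA receptor genes rose together: GID1A was 2.67-fold higher (1.42 ± 0.33, adjusted p = 0.0128), GID1C 2.58-fold (1.36 ± 0.31, adjusted p = 0.0122) and GID1B 1.76-fold (0.82 ± 0.20, adjusted p = 0.0157). SNE, a homologue of the F-box gene SLY1 that targets DELLA proteins for destruction, rose by 0.87 ± 0.19 and SPY, which encodes an O-fucosyltransferase acting on DELLA proteins, by 0.57 ± 0.17. Anthocyanin genes fell, DFR 23.9-fold (-4.58 ± 0.52) and UF3GT 12.4-fold (-3.63), and so did the jasmonate genes JMT (-1.94 ± 0.36) and OPCL1 (-1.10 ± 0.25). In all 4660 probe sets passed, 3029 higher and 1631 lower in the transgenic line, of which 2690 differed at least 2-fold.

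The GA perception and signalling list had 5 of 8 members higher past the threshold, and 5 adjusted over the list alone, with a median of 0.69. Its preset camera adjusted p was 0.0222, against an adjusted p of 0.348 with an estimated correlation, and it was 0.0561 without RGA-GR Dex replicate 3. Of 3 measured genes of the auxin list, with a median of 1.41, GH3.3 (1.41 ± 0.23) and GH3.5 (1.47 ± 0.35) rose, both genes of auxin conjugating enzymes. The related GH3.9 and GH3.17, outside the list and looked up after the data were seen, did not pass here. Of photosynthetic tissue, RCA, the Rubisco activase gene, rose by 1.17 and the antenna protein gene LHCB4.1 by 0.70, the whole of 2 measured, though LHCB4.1 no longer passed in 10 of 22 alternatives. The cold response gene COR15A fell (-1.55 ± 0.26), as did the stress response gene ZAT10 (-1.41 ± 0.38) and the sperm cell histone gene MGH3 (-1.86 ± 0.50), the 1 measured pollen gene of the lists fixed beforehand. Of the DELLA targets known from seedlings, 2 of 4 rose, GID1A and GID1B. The lists of stamen regulators, tapetum and pollen wall, cell wall loosening, cell cycle, trichomes, defence, heat shock and circadian clock had no member past the threshold over all probe sets, with medians of -0.03, -0.78, -0.36, 0.06, 0.69, 1.57, 0.07 and 0.53. The medians were -0.62 for abscisic acid and cold response, -4.10 for flavonoid synthesis, -1.52 for jasmonate biosynthesis, 0.94 for photosynthetic tissue, 0.37 for DELLA targets and -0.23 for touch and wounding. Adjusted over the list alone the calls in the lists fixed beforehand were the same, with CML38 higher in addition. TRY is the 1 measured gene of its list, so nothing is adjusted there: its unadjusted limma p was 0.0332, and 0.0926 adjusted over all probe sets.

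The largest rises with 1 gene per probe set were in AT1G19530, 108-fold (6.75 ± 1.19), the seed storage protein gene PAP85, 57.1-fold (5.83 ± 0.77), AT3G62950 (3.97), AT2G30600 (3.84, with 3.28 on its other probe set) and AT1G19540 (3.68). The largest falls were in AT1G72290, a Kunitz protease inhibitor gene, 71.6-fold (-6.16 ± 1.35, from -8.37 to -4.52 over the alternatives), AT5G62210 (-5.57), the thiol reductase gene GILT (-5.56), AT4G02250, a pectin methylesterase inhibitor gene (-5.51), and AT3G07820, a polygalacturonase gene (-5.17). All of these falls rest on uneven arrays. AT1G72290 had log2 ratios of -5.30 and -5.96 on RGA-GR Dex replicates 2 and 3 and 0.00 on replicate 1. On replicate 1 AT5G62210 stood at 0.45 and GILT, AT4G02250 and AT3G07820 at 0.00, against -2.70 to -5.12 on replicates 2 and 3. Over the alternatives AT3G07820 ranged from -7.30 to -4.08, AT5G62210 from -7.05 to -4.62, AT1G19530 from 5.36 to 7.55 and PAP85 from 4.19 to 6.46. The probe set of AT1G19530 has a median ratio under 1, so its divisor is not known. In the wider pollen list, 18 of 18 measured genes had lower means in RGA-GR Dex, 11 past the threshold and 14 adjusted over the list alone, with a median of -2.94. Examples are AT5G45880 (-4.43), AT1G29140 (-4.35) and the pectate lyase gene AT59 (-3.71), while the pollen actin gene ACT12 (-1.97) passed over the list alone and not over all probe sets. Pair 1 of the transgenic line showed least of this: the median log2 ratio of the list was 0.25 on RGA-GR mock replicate 1 and -0.29 on RGA-GR Dex replicate 1, against -1.32 and -3.08 in pair 2, -0.85 and -2.26 in pair 3, and 0.60 to 0.93 on the nontransgenic arrays. In the wider tapetum list, 7 of 22 fell and 1 rose, with a median of -0.25. SHT, the tapetal spermidine acyltransferase gene, fell by 2.01 on the log2 scale, ATA27 by 1.15, and AT5G52160 rose by 1.77. The preset camera adjusted p was 1.5e-08 for pollen and 0.0222 for tapetum, against an adjusted p of 0.165 and 0.432 with an estimated correlation. With a replicate block within the transgenic line the adjusted p with an estimated correlation was 0.0340 for pollen and 0.457 for tapetum.

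The transgenic arrays stood apart in control probe sets as well: 25S rRNA signal was 7.55 higher on the log2 scale in RGA-GR Dex than in nontransgenic Dex, and the nontransgenic arrays all belonged to the batch with spike-in signal. The count was 3762 with that batch as a block (2398 higher, 1364 lower) and 3144 in the 5 arrays with spike-in signal, where the split turned to 1466 higher and 1678 lower. Subtracting each array's median turned the split to 1751 higher and 2253 lower, against 65.0% higher as deposited, as it moved the median of all probe sets from 0.14 to -0.05. The count was 2906 after quantile normalization, 1874 without RGA-GR Dex replicate 2, 2961 and 3099 without nontransgenic Dex replicates 1 and 2, and 1134 without pair 2 of the transgenic line.

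**Figure D2:**
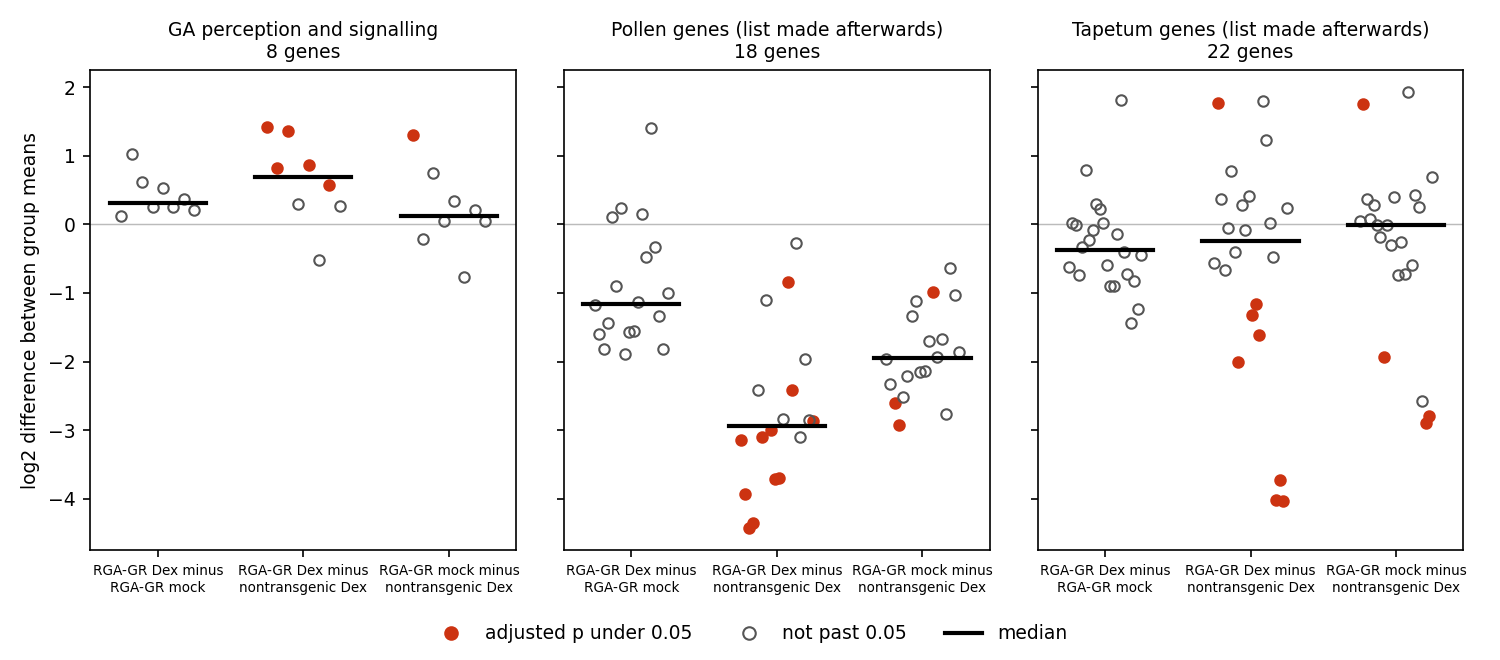
Log2 differences between group means (vertical axis) for each measured gene of 3 lists, in the 3 comparisons (horizontal axis). Filled points pass an adjusted p of 0.05, open points do not, and bars are medians. In RGA-GR Dex minus nontransgenic Dex, 5 of 8 GA genes are higher and 11 of 18 pollen genes lower past the threshold.

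The third comparison, RGA-GR mock against nontransgenic Dex, is a control pair in which neither group has both the transgene and Dex. DFR (-1.90 ± 0.52) and UF3GT (-3.62) were lower in the uninduced transgenic line too, as were OPCL1 (-1.39 ± 0.25), COR15A (-1.35 ± 0.26), ZAT10 (-1.71 ± 0.38) and MGH3 (-1.79 ± 0.50), and each fall passed the threshold. GID1A was 2.46-fold higher (adjusted p = 0.0297), the 1 of 8 genes of GA perception and signalling to pass here, and GH3.3 (0.87 ± 0.23, lost in 12 of 22 alternatives), RCA (1.19 ± 0.30) and LHCB4.1 (0.88 ± 0.21) rose. GH3.9, outside the lists, rose too (0.99, adjusted p = 0.0448), and was lost in 15 of 22 alternatives. GID1B differed by -0.21 ± 0.20 and did not pass. EMS1, a receptor kinase gene of anther cell fate, fell (-0.94 ± 0.26), the 1 of 3 stamen regulators to pass. In all 2635 probe sets passed, 1566 higher and 1069 lower, of which 1611 differed at least 2-fold.

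The largest rises were in PAP85, 34.0-fold (5.09 ± 0.77), AT1G13650 (4.82), AT4G09390 (4.06), the ACC oxidase gene AT1G12010 (3.66) and AT2G16670 (3.53). The largest falls were in AT1G71680, 47.3-fold (-5.56 ± 1.23, from -7.62 to -4.56 over the alternatives), AT4G12890 (-5.48), AT3G54520 (-4.83), the iron deficiency regulator gene BHLH101 (-4.35) and AT1G05040 (-4.33). Over the alternatives AT4G12890 ranged from -7.27 to -4.48 and AT3G54520 from -6.34 to -3.58. On the RGA-GR mock arrays AT1G71680 was uneven, with log2 ratios of -0.47, -3.60 and -4.86, and so was AT4G12890, with 0.25, -4.04 and -4.59. AT3G54520 ran from -5.28 to -1.82 there and BHLH101 from -3.60 to -0.75, while AT1G05040 ran from -4.47 to -3.40. These falls, and the rises of AT1G13650 and AT4G09390, come from probe sets with a median ratio under 1, whose divisor is not known. The wider pollen list had 18 of 18 means lower and 3 past the threshold, with a median of -1.95 and a preset camera adjusted p of 5.5e-06, against an adjusted p of 0.312 with an estimated correlation. The wider tapetum list had 3 falls and 1 rise among 22, and 4 falls and 2 rises adjusted over the list alone, with a median of -0.01. The GA list had a median of 0.13, and the other medians were 0.09 for DELLA targets, 0.28 for stamen regulators, -0.14 for tapetum and pollen wall, 1.03 for photosynthetic tissue, -1.11 for jasmonate biosynthesis, 0.87 for auxin response and -0.02 for cell wall loosening. For abscisic acid and cold response the median was -0.62, for the cell cycle 0.29, for trichomes 0.90, for flavonoid synthesis -2.76, for defence -0.18, for touch and wounding -0.95, for heat shock -0.35 and for the circadian clock 0.16. Adjusted over the list alone, JMT and GH3.5 passed in addition in the lists fixed beforehand. For TRY, alone in its list, the unadjusted limma p was 0.0088, and 0.0541 adjusted over all probe sets.

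In the same comparison the 25S rRNA signal was 4.95 higher and the 5S rRNA signal 1.91 higher in RGA-GR mock. The effect of Dex and that of the uninduced transgene cannot be told apart here, since no mock-treated nontransgenic plants are among the groups. The count fell to 0 without RGA-GR mock replicate 2, and it was 1341 without RGA-GR mock replicate 1 and 1164, 1116 and 1357 without nontransgenic Dex replicates 1, 2 and 3. It was 4927 with a replicate block within the transgenic line, 1412 with the spike-in batch as a block, and 1029 (192 higher, 837 lower) in the 5 arrays with spike-in signal. Subtracting each array's median gave 839 higher and 1412 lower, against 59.4% higher as deposited, and quantile normalization gave 1123 in all.

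**Figure D3:**
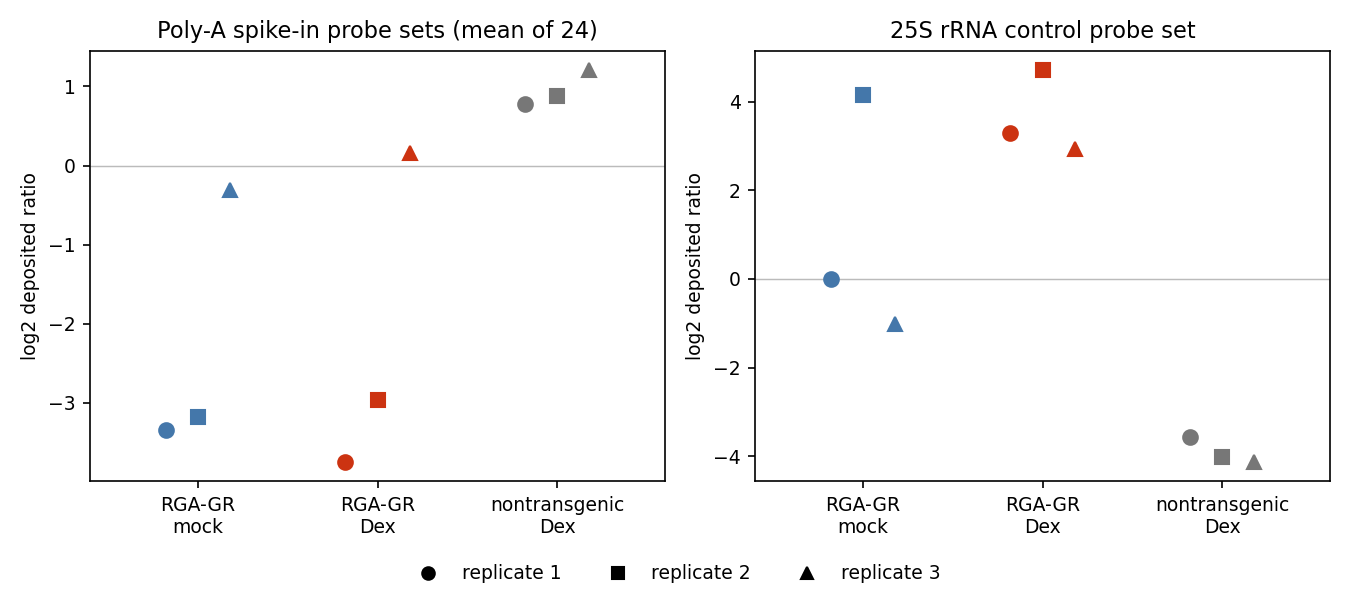
Log2 of the deposited ratio (vertical axes) of the poly-A spike-in probe sets, as a mean of 24, and of the 25S rRNA control probe set on each array, by group (horizontal axes). Points are arrays, shaped by replicate number. Spike-in signal is low on replicates 1 and 2 of both transgenic groups, and 25S rRNA signal is lowest on the 3 nontransgenic arrays.

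The last comparison asks which probe sets changed the same way in both Dex comparisons, the rule by which effects of Dex and of the T-DNA are left out. DFR, JMT and GID1B were the listed genes with matching signs and the lowest p values after Dex, and none counts, since no probe set passed in the first comparison. The count was 0, it was 1 with eBayes without trend (AT5G28090), and 15 without RGA-GR Dex replicate 1, 3 higher and 12 lower. In the 5 arrays with spike-in signal it was 43, all lower. Those 15 include AT1G15330 and BGLU46, higher, and AT5G62210, AT4G02250 and AT3G48490, lower. At an unadjusted p under 0.05, 909 probe sets passed in both comparisons in the same direction, where independent lists would share 321. Simulated unchanged groups that share the RGA-GR Dex arrays gave 221, but these groups hold no difference between the lines and no pairs of arrays, so they do not give the value to be had without an effect of Dex. Across probe sets, which are not independent replicates, the differences correlated with r = 0.516 against 0.50 in those unchanged groups, with a covariance of 0.270 against 0.113. Between the second comparison and the third, which share the nontransgenic arrays, r was 0.840 against 0.50 and the covariance 0.695 against 0.113. They shared 1349 rises and 820 falls, where independent lists would share 274.6 and 100.9, and part of the excess may come from the shared arrays.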

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

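Apart from the other splits of the arrays, the tests in this part were chosen after the patterns had been seen, and for nontransgenic arrays as a batch of their own, the spread between pairs, the number of arrays and the mix of flower stages, also after the deciding value had been seen.

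Signals of the rRNA and hybridisation control probe sets, which no comparison uses, had higher means in the transgenic line than in the nontransgenic control arrays, while the poly-A spikes had means lower by 2.48 to 3.97. The 25S rRNA control differed by 7.55 (SE 0.57) on the log2 scale for RGA-GR Dex and by 4.95 (SE 1.59) for RGA-GR mock, and RGA-GR Dex lay 2.60 (SE 1.67) above RGA-GR mock, higher in all 3 pairs. The 5S rRNA control differed by 1.60 (SE 0.47) for RGA-GR Dex and by 1.91 (SE 0.67) for RGA-GR mock. The hybridisation spikes bioB, bioC, bioD and cre differed by 0.82 (SE 0.24) for RGA-GR Dex and by 0.72 (SE 0.29) for RGA-GR mock, where replicate 3 (-0.29) lay below nontransgenic Dex replicate 1 (-0.24).

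The transgenic line differed from the nontransgenic Dex arrays in 4660 probe sets when treated with Dex and in 2635 when mock treated. The spike-in batch as the whole cause is argued against by transgenic replicate 3, if it shares the batch of the nontransgenic arrays. Over the probe sets called in replicates 1 and 2, its median signed difference was 0.684 to 0.769 times theirs, where a batch effect alone would bring it near 0. That the batch is shared is read only from spike-in signal, with ratios of 0.806 and 1.11 on replicate 3 and 1.72 to 2.30 on the nontransgenic arrays. Nontransgenic arrays as a batch of their own cannot be told apart from the transgene, because these arrays are the whole of their group. The lowest 25S rRNA signal on a transgenic array lay 2.56 above the highest on a nontransgenic array. In the hybridisation spikes RGA-GR mock replicate 3 overlapped the nontransgenic arrays. Neither value decides, and the 25S rRNA signal also depends on the RNA of the sample. The splits of 3 against 3 arrays are too few for a share under 0.05: of 10, only the real split gave as many, 4660 against 0 in the highest other, and for the mock group 1 of 10 did, 2635 against 0. An effect of the transgene, of its uninduced product, or of Dex in the case of the mock group stays open and was not tested.

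No probe set passed in RGA-GR Dex against RGA-GR mock with limma, while 1525 had an unadjusted p under 0.05. The spread between replicate pairs as the whole cause cannot be told apart: with a replicate block within the transgenic line the count was again 0, the lowest it can be, while the smallest adjusted p went from 0.143 to 0.0525. Too few arrays for the size of the differences cannot be told apart either: the simulation recovered 9.3% of 2-fold and 35.1% of 4-fold changes, and the sizes of the real ones are not known. RGA-GR Dex against nontransgenic Dex, with 10.2% of 2-fold changes recovered, gave 4660. The simulation changed only 200 of 17273 probe sets, and recovery depends on the share changed, so 10.2% is not the recovery behind that count. The 10 splits of these 6 arrays are too few for a share under 0.05: at an unadjusted p the real value was 1525 and the highest other 3213, with 4 of 10 as large, where the highest set mock 1, Dex 1 and mock 2 against the rest, largely following replicate pairs and the spike-in batch, and the others that part all 3 pairs gave 425 to 766. A real count of 0 is met by every regrouping, so 10 of 10 splits (highest other 1) and, for changes in both Dex comparisons, 100 of 100 regroupings (highest other 2169, with the nontransgenic arrays in the place of RGA-GR Dex) decide nothing.

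Pollen genes of the wider list had lower medians in the transgenic line, -2.94 under Dex with 11 of 18 past the threshold and -1.95 under mock treatment with 3 of 18, and as sets an adjusted p of 0.165 and 0.312 with an estimated correlation (0.0340 and 0.0552 with the replicate block within the line). Pair 1 showed least: the median log2 ratio was 0.25 on mock 1 and -0.29 on Dex 1, against -3.08 to -0.85 in pairs 2 and 3 and 0.60 to 0.93 on the nontransgenic arrays. Scaling of the arrays as the cause of the lower medians is argued against by quantile normalization and array medians subtracted, under which the highest was -1.80. The spike-in batch is argued against by the 5 arrays with that signal, where the higher median was -2.17 and at least 16 of 18 genes were lower. This holds only if those 5 arrays share a batch, and nontransgenic arrays as a batch of their own cannot be told apart here either. Another mix of flower stages may be the cause and cannot be told apart: tapetum genes, active before pollen matures, had a median of -0.25 with members moving both ways, and the stages within each sample are known only up to the limit in the labels. A response of pollen genes to RGA, as a biological explanation, stays open and was not tested apart from the transgene itself.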

How the results depend on the processing

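The replicate block within the transgenic line, the spike-in block, the fits to the arrays with and without spike-in signal and the fit without pair 2 were chosen after seeing the data, and the other alternatives were planned. Direction held for all named genes past the threshold, and DFR, GH3.3, COR15A and SNE stayed past it in all 22 alternatives for RGA-GR Dex against nontransgenic Dex. Among those that did not, LHCB4.1, AT59 and ATA27 were lost in 10 of 22 and SPY in 9 there, and for RGA-GR mock against nontransgenic Dex GH3.3 and AT4G09390 were lost in 12 and EMS1, MGH3, RCA and DFR in 9 each. Over the alternatives set beforehand, gene values no longer passed in 95 cases in that comparison and in 223 for RGA-GR mock against nontransgenic Dex, each in the same direction. Where the cause of a move is not its construction (fewer arrays, a higher threshold), the cause was not tested. An array left alone in its group is assumed to vary like the others. Signal over background cannot be read from ratios, and the number of arrays limits precision.

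For Dex against mock the count was 0, but 1 with eBayes without trend, 50 in the 5 arrays with spike-in signal, and 0 to 15 as each array was left out. For changes in both Dex comparisons these were 1, 43 and 0 to 15. For RGA-GR Dex against nontransgenic Dex the count of 4660 was 2906 with quantile normalization, 2690 at 2-fold, 1134 without pair 2, and 1874 to 4881 with an array left out. For RGA-GR mock against nontransgenic Dex the count of 2635 was 1123 with quantile normalization, 1611 at 2-fold, 1412 with spike-in presence as a block, 1029 in the 5 arrays with that signal, 0 without pair 2, and 0 to 2773 with an array left out. Of the quantile calls, 2884 and 1123 were also called as deposited. With a replicate block within the transgenic line the counts were 0, 6626 and 4927. The block over all 9 arrays gave 0, 5131 and 3181. The pairing changed no other count by over 1.5 times.

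Sign changes of medians were followed only in lists with at least 5 measured genes. Medians of smaller lists that lie near 0 can change sign too, since subtracting array medians moves all differences of a comparison together. In the larger lists, the GA list changed sign in mock against nontransgenic Dex (-0.010 with array medians subtracted). The wider tapetum list did so there as well (0.10 without RGA-GR mock replicate 1 and without nontransgenic Dex replicate 1, in a range of -0.17 to 0.10 with an array left out, 0.065 with the spike-in block, 0.13 in the 5 arrays). The plastid-encoded median became -0.11 without RGA-GR mock replicate 1 and -0.33 without RGA-GR Dex replicate 3 in Dex against mock (-0.33 to 0.81 with an array left out). It became 0.32 without RGA-GR Dex replicate 1 (-1.02 to 0.32), 0.81 with the spike-in block and 0.79 in the 5 arrays for RGA-GR Dex against nontransgenic Dex, and 0.67 and 0.63 in the last 2 settings for RGA-GR mock. Among genes not past the threshold, XTH18 became -0.14 without RGA-GR mock replicate 1 (-0.14 to 2.03) and GID1C -0.0056 in the 5 arrays, both in Dex against mock. Against nontransgenic Dex, RGA-GR Dex gave XERICO 0.032 with the spike-in block and 0.074 in the 5 arrays, and SPL -0.0029 there.

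Not every planned gene difference is covered by these statements. After sign changes had been seen, 59 differences that were not past the threshold and no larger than their SE were set apart. Their values are printed only where a list has 1 measured gene, in a median, or for UF3GT in Dex against mock. These 59 differences changed sign 132 times under the alternatives, 88 of these under planned ones, against 5 among the 214 differences kept. Of the 59, 1 (XTH18 for RGA-GR Dex against nontransgenic Dex, in the 5 arrays) passed the threshold.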

Other observations

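The gene families and plastid-encoded genes in this part were grouped, and their tests chosen, after the data had been seen.

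Genes of subtilases, a family of secreted proteases, differed between the uninduced transgenic line and nontransgenic Dex plants: 4 of 6 measured fell and 1 rose. SBT4.13 fell by 3.71 on the log2 scale, SBT3.3 by 1.83, SBT3.5 by 1.64 and SBT5.4 by 1.05, while SBT3.12 rose by 1.43. Among 36 families, against 562 falls in 9490 genes, the enrichment had an adjusted p of 0.00597 (exact hypergeometric test), while the preset camera adjusted p was 0.213, with an adjusted p of 0.945 with an estimated correlation, and no probe set passed in this comparison without RGA-GR mock replicate 2. All 5 kept their direction with array medians subtracted and with quantile normalization, where SBT4.13, SBT3.5 and SBT3.12 no longer passed. After Dex against mock, the RALFL genes of small signalling peptides had a median of -0.43 over 8 genes (preset camera adjusted p = 0.0407) and the GSTU glutathione transferase genes a median of -0.57 over 8 (adjusted p = 0.0478). Both had an adjusted p of 0.592 with an estimated correlation, and no single member passed. The medians were -0.49 and -0.60 after quantile normalization and -0.48 and -0.62 with array medians subtracted. In RGA-GR Dex against nontransgenic Dex, RALFL25 (-3.40), GSTU20 (-2.94) and GSTU25 (-2.50) fell and GSTU16 rose (1.31). The 3 GSTU genes passed the same way in RGA-GR mock against nontransgenic Dex (GSTU20 -2.19, GSTU25 -2.44, GSTU16 1.01), where GSTU18 (0.95) and GSTU27 (0.88) rose too and RALFL25 (-1.73) did not pass. In that comparison GSTU16 was lost in 15 and GSTU27 in 17 of 22 alternatives.

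Genes encoded in the plastid differed between arrays of the same group. Their median log2 ratio over 68 genes was -1.05 on RGA-GR mock replicate 1, -1.26 on RGA-GR Dex replicate 1 and -0.58 on RGA-GR mock replicate 2. It was 0.00 on RGA-GR Dex replicate 2, 0.57 on RGA-GR mock replicate 3 and 0.90 on RGA-GR Dex replicate 3, and 0.00 to 0.29 on the nontransgenic arrays. The median difference was 0.22 for Dex against mock, -0.23 for RGA-GR Dex against nontransgenic Dex and -0.57 for RGA-GR mock, with preset camera adjusted p values of 0.242, 0.229 and 0.0747, and an adjusted p of 0.811, 0.806 and 0.695 with an estimated correlation. With a replicate block within the transgenic line the preset values were 0.0174, 0.0388 and 0.000718, against an adjusted p of 0.397, 0.457 and 0.456 with an estimated correlation. Singly, 0 members passed for Dex against mock, 5 passed higher and 0 lower for RGA-GR Dex against nontransgenic Dex, against the direction of the median, and 2 higher and 1 lower for RGA-GR mock.

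The median SD of log2 ratios within a group was 0.219 for nontransgenic Dex, 0.329 for RGA-GR Dex and 0.323 for RGA-GR mock. The RGA-GR Dex arrays lay above the other 6 in 783 probe sets (4.53%) and below in 343 (1.99%), and the RGA-GR mock arrays in 242 (1.40%) and 227 (1.31%). The 3 nontransgenic arrays lay above the others in 2084 and below in 3231.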
